A study of Mus musculus with 18 samples.

How the data were processed

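Total RNA was measured on 18 Affymetrix MoGene 2.0 ST arrays, whole-transcript mouse arrays with 1 colour. Per the labels' protocols, muscle cells of C57BL/6 mice with floxed alleles of Srf (flox/flox, in which the Cre recombinase deletes the stretch between the recognition sites) were transduced 2 times with an adenovirus carrying GFP alone (Ad-GFP, called WT) or GFP and Cre (Ad-Cre-GFP, called KO). Srf encodes serum response factor, a transcription factor that binds CArG boxes and acts with actin-sensing (MRTF) and MAP-kinase-regulated (TCF) partners. GFP-positive cells were sorted 2 days after the first transduction, plated on matrigel (1 mg/mL) in growth medium for 24 h, and then moved to medium with 2% horse serum, in which myoblasts leave the cell cycle and fuse into myotubes. RNA was taken at day 0, before the change of medium, and at days 1 and 3 after it, in 3 replicates per group. Single-stranded cDNA was amplified from 100 ng of RNA by the Ovation PicoSL V2 protocol. Groups and replicate numbers were taken from the sample titles and characteristics. The labels say that experiments were done in triplicate and not what makes up a replicate, so the p-values measure the spread between these samples, which may be partly technical.

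The values deposited by the authors are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, RMA (background correction, quantile normalization and summary of probes) and Partek were used, with versions not given in the sources used here. The array medians ranged from 4.69 to 4.76 and no gene centring was seen, since values ran from about the array floor to about 13. Probe sets are named by an Entrez gene number, 1 per gene. Of 25206 probe sets, 23185 had exactly 1 gene symbol in the platform annotation, 0 had several and 2021 had none. The symbols were looked up by Entrez number in the RefSeq gene table of GRCm38.p6, and 0 had to be changed. The array design's genome build is not given in the sources used here, so no coordinates are printed. An array gives no detection call here, and no signal floor was set. Log2 changes are differences of array values. A mean below the array medians is not shown to lie above background, so a log2 change against such a mean is a lower bound at most, its place among the largest changes depends on the background, and no fold is printed for it. The genes concerned are named beside their values. The number of arrays limits the precision.

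The 23185 named genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in 1 model with 6 group means over all 18 arrays, with no block and no filter on dim genes. This gave 12 residual degrees of freedom and a prior worth 5.34 more. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from this fit. The comparisons were KO against WT on each day, days 1 and 3 against day 0 within WT and within KO, and the difference of the KO effect between days. Values are given as mean ± SD on the log2 scale with n = 3 arrays, and changes as log2 differences with their standard error. The WT cells received no Cre, so effects of Cre and effects of the loss of Srf cannot be told apart in this design.

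Gene lists were fixed before the data were examined. They cover SRF cytoskeletal targets, SRF immediate early targets, actin nucleation and turnover, focal adhesion and integrins, YAP/TEAD targets, satellite cells and undifferentiated myoblasts, myogenic transcription factors, sarcomere and excitation-contraction, myoblast fusion, cell cycle, cell cycle inhibitors, interferon response, p53 targets, extracellular matrix, cholesterol synthesis, inflammatory cytokines, and markers of 6 other cell types (fibro-adipogenic, adipocyte, endothelial, macrophage and leukocyte, pericyte, Schwann). Lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison, and again with the correlation estimated from the residuals and with fry. A list written from general knowledge can hold genes that others share, and some genes stand on more than 1 list. In the KO against WT comparisons and the differences between days, 14 list calls held with both the preset and the estimated correlation and 18 with the preset one alone.

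Named genes follow a rule fixed at the same time. Srf is given first. For each KO against WT comparison the rule takes the 10 genes with the largest rise and the 10 with the largest fall among called genes whose 3 arrays of one group all lie above the 3 of the other. For comparisons over time and differences of effects it takes 5 and 5. For each list it takes the 4 called members with the largest change or, where none was called, the 2 with the highest mean, as values. Predicted genes, small RNAs and olfactory or vomeronasal receptors were counted and not named. A named gene may be followed in other comparisons.

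The fit was tested on simulated data made from these arrays' means and spreads, with 67 genes changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale among 23185 per day. For KO against WT at day 0, 32.8% of the genes changed by 0.5 on the log2 scale were recovered, 86.6% of those changed by 1 and 100% of those changed by 2. At day 3 the shares were 23.9%, 89.6% and 100%, and at day 1 they were 31.3%, 100% and 100%. False calls made up 4.58%, 7.78% and 5.33% of all calls at days 0, 1 and 3. Of 20 simulated lists of 30 genes shifted by 0.3 at day 3, 20 were called, and 0 of the 100 unshifted ones. The simulated genes varied independently, so this does not show how often lists of genes that vary together are called falsely. The simulation had no pairing of replicates either.

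Alternatives were quantile normalization, median centring and cyclic loess on top of the deposited values, only the genes above the median by mean level, all probe sets with or without a name, only the arrays of the groups compared, eBayes with trend and robust settings, array weights, the replicate number as a block, culture as a random block, a minimum log2 change of 1, an adjusted p under 0.01, and leaving out each array in turn. Numbers shared between KO and WT were checked for pairing by correlating the deviations of same-numbered arrays from their group means across genes. At day 3 the 3 correlations were 0.33, 0.15 and 0.22. The numbers were therefore taken as pairs there in permutations and in an added block, and not in the main fit. At day 0 the correlations were 0.19, 0.09 and 0.1, and at day 1 they were 0.26, -0.05 and -0.02. The day 0 values are all positive too, and no limit for pairing was stated, so pairing at day 0 is not excluded. Labels of day 0 were exchanged freely in the permutations, and pairing there would raise the smallest p that these can give. Between days, same-numbered arrays had a median correlation of 0. After the data were seen, a replicate block within each day was added, as were the removal of the array farthest from its group median on each day (day 0 KO replicate 2, day 1 WT replicate 3 and day 3 WT replicate 1), permutation tests of Srf, and gene families defined by symbol. No pair of arrays was identical, and the smallest root mean square difference between 2 arrays was 0.253.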

Results

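The data set holds expression values of 23185 named genes in floxed-Srf mouse muscle cells, 3 arrays in each of 6 groups. The groups are WT (Ad-GFP) and KO (Ad-Cre-GFP) cells at day 0 in growth medium and at days 1 and 3 of differentiation. Arrays of one group correlated with each other at r = 0.987 to 0.994 across genes, and KO with WT arrays of the same day at 0.984 to 0.994. The first principal component took 67.2% of the variance and separated day 0 from days 1 and 3. The design asks which genes depend on SRF before and during differentiation, and whether the differentiation response itself depends on it.

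Srf, the targeted gene, was lower in KO cells on every day. Its mean was 8.43 ± 0.12 in WT and 8.05 ± 0.22 in KO at day 0 (SD, n = 3), 8.52 ± 0.11 and 8.11 ± 0.06 at day 1, and 8.28 ± 0.18 and 7.79 ± 0.20 at day 3. The 9 KO arrays all lay below all WT arrays of their day. The differences were -0.38, -0.40 and -0.49 on the log2 scale, which is 1.3-, 1.32- and 1.4-fold. They missed the threshold over all genes (adjusted p = 0.391, 0.514 and 0.136) and had adjusted p-values of 0.0112, 0.0108 and 0.00566 when adjusted over the 3 days alone. For the mean difference of -0.42, a two-sided exact permutation test that exchanges day 3 labels only within same-numbered pairs gave p = 0.000625, the smallest value that its 3200 relabellings can give. With labels exchanged freely within days p was 0.00025, the smallest that 8000 relabellings can give. Both permutation tests were added after the separation of the arrays had been seen, which fixes them at their smallest p. The labels do not say which exons Cre removes, and a probe set that also reads retained exons can keep signal, so these values do not measure how much functional Srf was left.

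**Figure D1:**
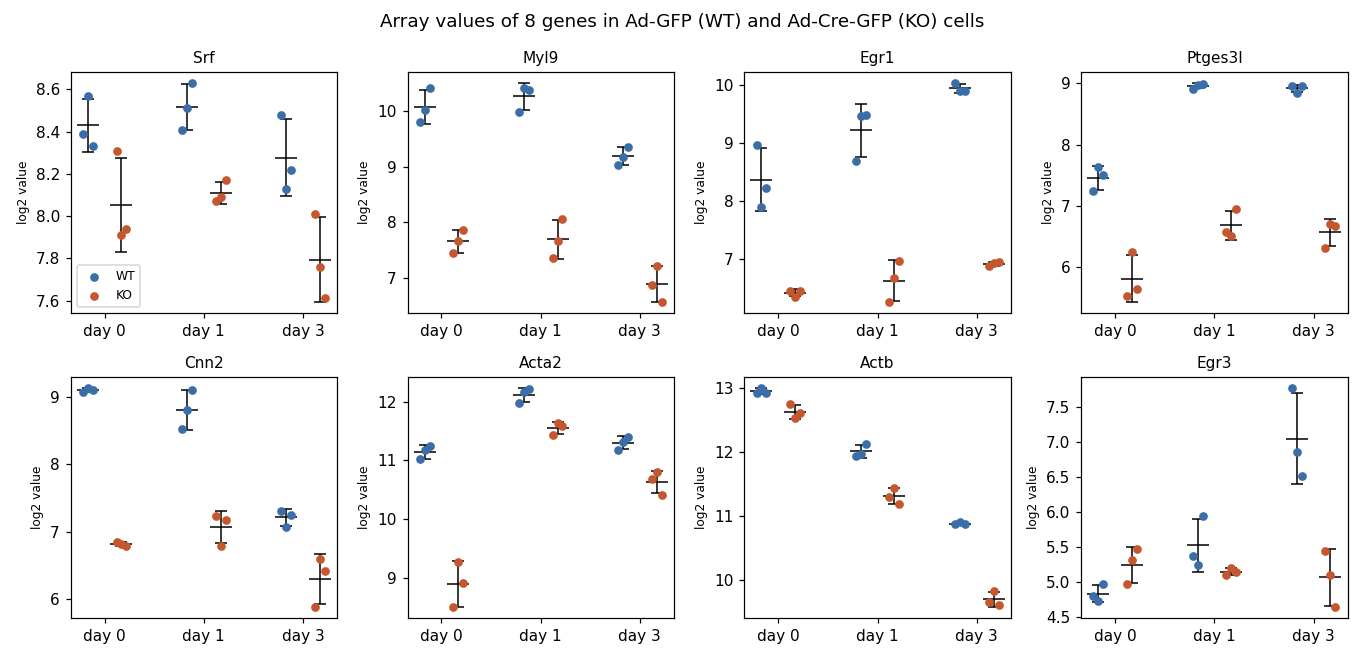
Log2 array values (vertical axis) of 8 genes by day for WT (blue) and KO (orange) cells, with each point 1 array and black bars the mean ± SD of 3 arrays. Myl9, Egr1 and Ptges3l were lower in KO on every day, the Acta2 and Cnn2 differences were largest at day 0, and those of Actb and Egr3 were largest at day 3.

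At day 0, before the change of medium, 56 of 23185 genes were higher and 58 lower in KO. Myl9, a regulatory myosin light chain, fell 5.34-fold, from 10.08 ± 0.31 to 7.66 ± 0.21 (log2 change -2.42, SE 0.20, adjusted p = 5.61e-06). Cnn2, the actin-binding calponin 2, fell 4.93-fold, from 9.11 ± 0.03 to 6.81 ± 0.02, and Acta2, smooth muscle actin, fell 4.73-fold, from 11.14 ± 0.12 to 8.90 ± 0.38. The focal adhesion protein gene Tgfb1i1 (also called Hic-5) changed by -1.83, Pdlim7 by -1.24 and the zinc finger transcription factor gene Egr1 by -1.95. Further genes with large falls were Ckm, muscle creatine kinase (-1.98), Mstn, which encodes the muscle growth inhibitor myostatin (-1.65), Ptges3l (-1.65) and Sh3bgr (-1.26). The largest rises in array values were those of Ly6d, from 4.44 ± 0.08 to 6.54 ± 0.55 (log2 change 2.10, SE 0.22, adjusted p = 8.29e-05), and Krt18, a keratin of simple epithelia, from 6.60 ± 0.38 to 8.44 ± 0.19 (3.56-fold). Gal, the neuropeptide galanin, rose by 1.79, Fabp4, a fatty acid binding protein, by 1.70, Pde2a by 1.67, Tinagl1 by 1.62, the iron-siderophore binding protein gene Lcn2 by 1.58, the chemokine gene Ccl5 by 1.35, the solute carrier gene Slc4a11 by 1.34 and the water channel gene Aqp3 by 1.33. The WT means of Ly6d, Pde2a, Tinagl1, Lcn2 and Aqp3 lay below the array medians.

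Among the fixed lists at day 0, SRF cytoskeletal targets had the smallest p. Of 39 measured members 12 fell, 0 rose and 27 were not called, with a median change of -0.36 (camera adjusted p = 5.54e-29, and 3.4e-05 with an estimated correlation). When adjusted over the list alone, 21 were lower and 1 higher. Of the 25 focal adhesion genes 1 fell, Fermt2 (kindlin-2, an integrin activator), by 0.87, with a list median of -0.10 (adjusted p = 0.00154, and 0.0116 with an estimated correlation). Of the 17 immediate early targets 1 fell, Egr1, and the list was not called (adjusted p = 0.3). The 20 myogenic transcription factors had a median of -0.23 with 0 members called (adjusted p = 4.79e-06, and 0.00156 with an estimated correlation), and 2 lower when adjusted over the list alone. Myog stood at 10.74 ± 0.23 in WT and 9.90 ± 0.70 in KO. Of 53 sarcomere and excitation-contraction genes 3 fell, namely Ckm, Jph1 (junctophilin 1, -0.94) and Cacng1 (a calcium channel subunit, -0.68), and 14 when adjusted over the list alone. The list's median was -0.42 (adjusted p = 7.98e-22), a call that was lost with an estimated correlation (adjusted p = 0.132). The list means of the 3 KO arrays were 7.39, 8.24 and 8.20, against 8.09, 8.47 and 8.61 in WT, and without KO replicate 1 the median was -0.13, with the preset call kept (adjusted p = 9.7e-06). In the other direction, the 30 interferon response genes had a median of 0.19 with 1 member called, Ccl5 (adjusted p = 4.79e-06, and 0.0013 with an estimated correlation). By their mean over all arrays only 10 of the 30 lay above the median level of all genes, and the others are not shown to lie above background. Of 22 inflammatory cytokine genes 2 rose, Lcn2 and Ccl2 (1.24), and the list was not called (adjusted p = 0.175). YAP/TEAD targets, in which F3 (tissue factor) changed by -0.74, p53 targets (median 0.11) and cholesterol synthesis (median -0.13) were called with the preset correlation (adjusted p = 0.00949, 0.00686 and 0.00579) and not with an estimated one (adjusted p = 0.171, 0.108 and 0.227). The YAP/TEAD call was also lost without WT replicate 1 (adjusted p = 0.0639) or KO replicate 2 (adjusted p = 0.0758), and its median of -0.10 was -0.16 without WT replicate 2. Without KO replicate 1 the p53 and cholesterol lists were not called with the preset correlation either (adjusted p = 0.085 and 0.072), and the cholesterol median was -0.07. The lists for actin nucleation, satellite cells, fusion, cell cycle, cell cycle inhibitors and extracellular matrix held 0 called genes and were not called (adjusted p = 0.698, 0.3, 0.0686, 0.565, 0.698 and 0.463). Of the 6 lists for other cell types none was called (adjusted p from 0.565 to 0.836). Fabp4 was the 1 called gene in them, and the adipocyte list that holds it had a median of -0.03.

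The day 0 count fell from 114 to 56 without KO replicate 1, 57 without KO replicate 3, 62 without WT replicate 2 and 66 without WT replicate 3. With only the arrays of these groups in the model it was 48. The calls of Pde2a, Lcn2, Mstn, F3, Cacng1 and Ccl2 were each lost without at least 3 of the arrays left out in turn, with the direction unchanged.

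**Figure D2:**
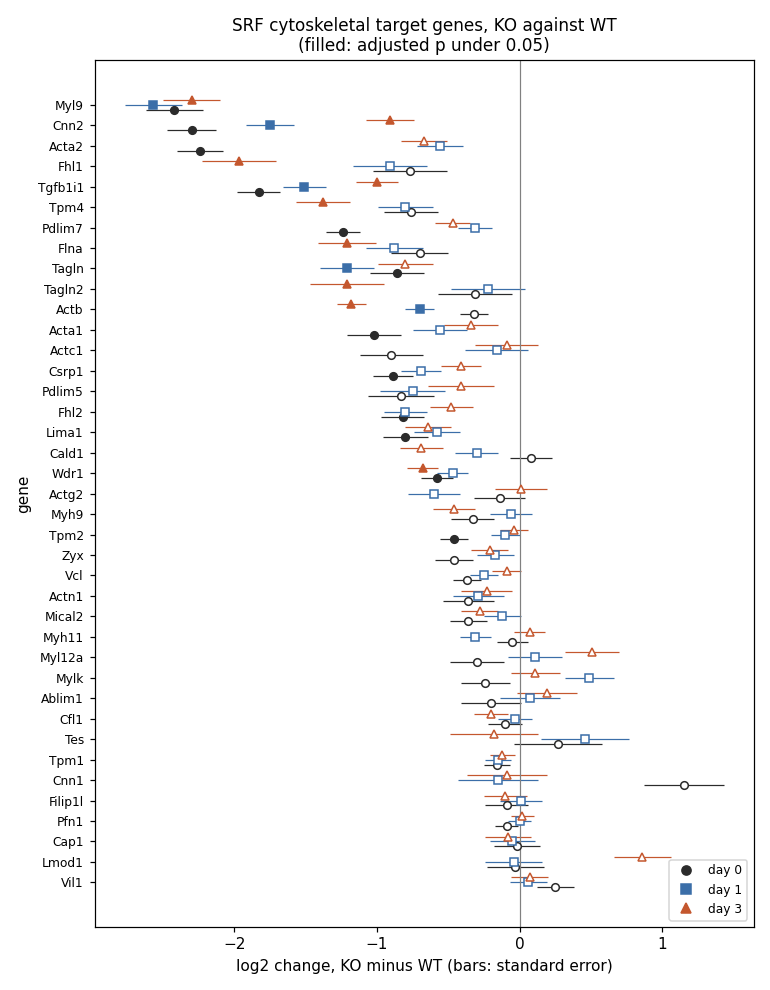
Log2 change between KO and WT (horizontal axis, bars the standard error) of the 39 measured SRF cytoskeletal targets at day 0 (black circles), day 1 (blue squares) and day 3 (orange triangles), filled where the adjusted p was under 0.05. There were 12 called members at day 0, 5 at day 1 and 9 at day 3, all of them lower in KO.

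At day 1 of differentiation 9 genes were higher and 12 lower in KO. Egr1 fell 6.01-fold, from 9.21 ± 0.45 to 6.63 ± 0.36 (log2 change -2.59, SE 0.23, adjusted p = 2.3e-05), and Myl9 5.93-fold, from 10.26 ± 0.24 to 7.70 ± 0.35 (adjusted p = 3.68e-06). Ptges3l changed by -2.27, Cnn2 by -1.75, Tgfb1i1 by -1.51, Cbr2, a carbonyl reductase, by -1.39, Tagln (transgelin, or SM22) by -1.21, Igfbp7 by -1.11, Actb (cytoplasmic beta-actin) by -0.70 and Fermt2 by -0.69. The rises were those of Timp3, an inhibitor of metalloproteinases, from 4.97 ± 0.65 to 6.72 ± 0.21 (log2 change 1.75, adjusted p = 0.023), Ackr3, an atypical chemokine receptor (1.23), Fosl1, an AP-1 subunit (1.15), Gpnmb (1.14), Ecm1 (1.06), Mpdu1 (0.77), Ly6e (0.77), the pro-apoptotic gene Bcl2l11 (0.70) and Ifitm3 (0.66).

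Of the 39 SRF cytoskeletal targets 5 fell and 34 were not called at day 1, with a median of -0.29 (camera adjusted p = 6.08e-22, and 0.000145 with an estimated correlation). Adjusted over the list alone, 19 were lower and 1 higher. The cholesterol synthesis list had a median of -0.27 over 20 genes with 0 called (adjusted p = 2.36e-10, and 0.0246 with an estimated correlation), and 2 lower when adjusted over the list alone. Its array means were 8.72, 8.75 and 8.86 in WT and 8.49, 8.57 and 8.50 in KO. Immediate early targets (median -0.13, 1 gene lower, Egr1), focal adhesion genes (median -0.09, 1 lower, Fermt2) and sarcomere genes (median -0.11, 0 called) were called with the preset correlation (adjusted p = 0.00236, 0.0277 and 0.0067), but not with an estimated one (adjusted p = 0.285, 0.0844 and 0.794). All 3 were lost with the preset correlation without WT replicate 2 (adjusted p = 0.0904, 0.314 and 0.0904). Focal adhesion was also lost without KO replicate 1 (adjusted p = 0.0907), and the sarcomere list without WT replicate 1 (adjusted p = 0.138) or KO replicate 2 (adjusted p = 0.317). The immediate early median was -0.06 without WT replicate 2, -0.07 without KO replicate 2 and -0.20 without WT replicate 1 or KO replicate 3. The sarcomere median was -0.05 without KO replicate 2 and -0.18 without WT replicate 3. Myog stood at 11.78 ± 0.05 in WT and 11.86 ± 0.06 in KO, and the fusion gene Mymk (Myomaker) at 12.32 ± 0.02 in WT and 12.39 in KO. The fusion and myogenic factor lists had medians of -0.03 and 0.01 (adjusted p = 0.727 and 0.607). In the extracellular matrix list 1 gene rose, Timp3, and the list was not called (adjusted p = 0.927). The interferon, p53, YAP/TEAD, satellite cell, cytokine, cell cycle, cell cycle inhibitor and actin nucleation lists had 0 called genes and adjusted p-values from 0.0841 to 0.908. The 6 lists for other cell types had 0 called genes and adjusted p-values from 0.158 to 0.959.

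The cell cycle list, which was not called, had array means of 6.18, 6.86 and 6.20 in KO and 6.28, 6.35 and 6.69 in WT at day 1. Without KO replicate 2, the array with 6.86, the day 1 count fell from 21 to 8, and without WT replicates 1 or 2 to 13 or 12. It rose to 32 without day 3 WT replicate 1, and with only the day 1 arrays in the model it was 9. Of the 9 rises, those of Ackr3, Mpdu1 and Bcl2l11 were each lost in at least 13 of the 18 fits that left out 1 array.

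At day 3, 18 genes were higher and 85 lower in KO. With quantile normalization on top of the deposited values 30 were higher and 85 lower. Egr1 fell 8.17-fold, from 9.95 ± 0.07 to 6.92 ± 0.04 (log2 change -3.03, SE 0.23, adjusted p = 2.94e-06). Egr3 changed by -1.98 and Egr2 by -1.65. Ptges3l fell 5.07-fold, from 8.91 ± 0.06 to 6.57 ± 0.22, and Myl9 4.92-fold, from 9.19 ± 0.17 to 6.89 ± 0.32. Fgfbp1, a carrier of fibroblast growth factors, changed by -2.30, Fhl1, a LIM-domain protein of striated muscle, by -1.97, Car3, the carbonic anhydrase of muscle, by -1.84 from 11.83 ± 0.14, Xirp2, an actin-binding protein of muscle attachment sites, by -1.60, and Timp1, an inhibitor of metalloproteinases, by -1.59. The rises were led by Ache, acetylcholinesterase, from 6.65 ± 0.34 to 8.18 ± 0.33 (2.89-fold, adjusted p = 0.0316), Ppp1r27, a regulatory subunit of protein phosphatase 1, from 8.25 ± 0.34 to 9.76 ± 0.19 (2.84-fold, adjusted p = 0.00324), and the antiviral gene Rsad2 (viperin), from 4.37 ± 0.35 to 5.86 ± 0.62. Gpnmb rose by 1.09, Krt18 by 1.04, Sting1, the adaptor of cytosolic DNA sensing, by 1.02, Tslp, a cytokine, by 0.94, Ropn1l by 0.93, the mitochondrial carrier gene Slc25a10 by 0.77 and Gstm2, a glutathione transferase, by 0.76. The KO means of Fgfbp1 and Egr2 and the WT means of Rsad2 and Gpnmb lay below the array medians.

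Of the 39 SRF cytoskeletal targets 9 fell at day 3 and 30 were not called. They included Tpm4 (-1.38), Tagln2 (-1.21) and Actb (-1.18), and the median was -0.28 (camera adjusted p = 2.59e-15, and 0.000859 with an estimated correlation). Adjusted over the list alone, 17 were lower and 2 higher. Of the 17 immediate early targets 4 fell, Egr1, Egr2, Egr3 and Arc (-0.68), with a median of -0.20 (adjusted p = 9.02e-06, and adjusted p = 0.055 with an estimated correlation), and 6 were lower and 2 higher when adjusted over the list alone. That median was -0.32 without WT replicate 1 and -0.31 without KO replicate 3. Of 38 extracellular matrix genes 3 fell, Timp1, the collagen gene Col8a1 (-0.95) and the membrane metalloproteinase gene Mmp14 (-0.93), with a median of -0.20 (adjusted p = 5.22e-06, and 0.0272 with an estimated correlation). The KO mean of Col8a1 lay below the array medians, and the list median was -0.13 without WT replicate 2. The focal adhesion list had a median of -0.09 with 0 called (adjusted p = 0.00263, and 0.0186 with an estimated correlation), and of -0.14 without KO replicate 1. The cholesterol synthesis list was higher in KO, with a median of 0.36 and 1 of 20 members called, Mvk, mevalonate kinase (0.45), and 11 higher when adjusted over the list alone (adjusted p = 2.38e-10, and 0.0164 with an estimated correlation). The interferon list was again higher, with a median of 0.17 and Rsad2 called (adjusted p = 4.79e-05, and 0.00404 with an estimated correlation). The cell cycle list had a median of -0.39 with 0 of 38 called (adjusted p = 2.39e-07), a call lost with an estimated correlation (adjusted p = 0.423). Its array means were 5.94, 5.59 and 5.35 in WT and 5.31, 5.38 and 5.15 in KO, and without WT replicate 1 the median was -0.13, with the preset call kept (adjusted p = 0.00798).

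At day 3 the lists for the contractile apparatus and for fusion were not called. The sarcomere list had a median change of -0.05 and 0 of 53 called (adjusted p = 0.296), and its array means were 10.63, 10.71 and 10.68 in WT and 10.61, 10.58 and 10.56 in KO. Mymk stood at 12.28 ± 0.03 in WT and 12.27 ± 0.03 in KO, 0.39 under the highest named genes in both, where a difference can be compressed. In the sarcomere list 18 of 53 genes, and in the fusion list 2 of 29, lay within 1 of those highest values. Mymx (Myomixer) stood at 8.35 ± 0.21 and 8.76 ± 0.24. The fusion list had 0 of 29 called (adjusted p = 0.37), and the myogenic factors 0 of 20 (adjusted p = 0.159). The remaining lists, for YAP/TEAD, satellite cells, actin nucleation, p53, cell cycle inhibitors and cytokines, had 0 called genes and adjusted p-values from 0.296 to 0.962, and the 6 lists for other cell types 0 called genes and adjusted p-values from 0.21 to 0.669. Same-numbered KO and WT arrays deviated together at this day. With the replicate number as a block within each day, 44 genes were higher and 144 lower, and no list call of day 3 changed. The count of 103 fell to 50 without WT replicate 2 and 51 without KO replicate 2, and rose to 217 without KO replicate 1. With only the day 3 arrays in the model it was 20. The calls of Egr2, Xirp2, Ropn1l, Tagln2, Mmp14 and Mvk were each lost in at least 10 of the 18 fits that left out 1 array.

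Over the 3 days 212 genes were called on at least 1 day, 191 of them on exactly 1. The 5 genes lower in KO on all 3 days were Myl9, Cnn2, Egr1, Tgfb1i1 and Ptges3l, and 0 genes were higher on all 3. Of the 12 genes lower at day 1, 8 were also lower at day 3, where independent lists would share 0.044, namely Actb, Cbr2, Cnn2, Egr1, Igfbp7, Myl9, Ptges3l and Tgfb1i1. Days 0 and 3 shared 9 lower genes (0.213 for independent lists) and 1 higher gene, Krt18. Days 1 and 3 shared 1 higher gene, Gpnmb, and days 0 and 1 shared 3, Bcl2l11, Ecm1 and Mpdu1. Days 0 and 1 shared 8 lower genes (0.03 for independent lists), among them Fermt2 and Tagln. The calls of all days share 1 estimate of the spread per gene, so the lists are not independent and these expectations are only a rough reference. Across all genes, which are not independent replicates, the KO effects of days 0 and 1 correlated at r = 0.21, of days 0 and 3 at 0.12 and of days 1 and 3 at 0.24.

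**Figure D3:**
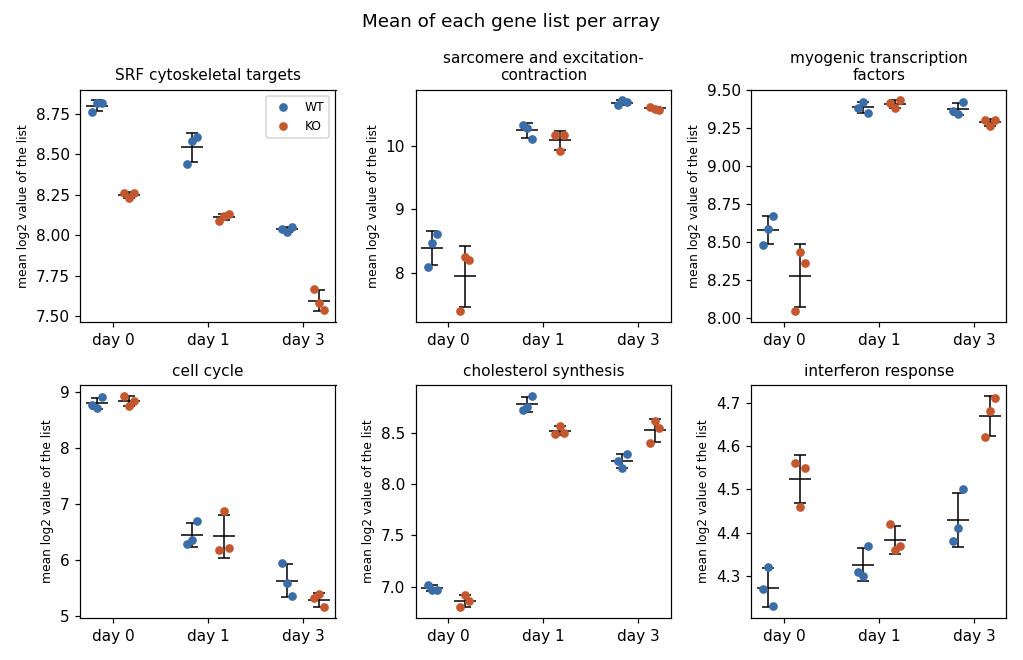
Mean log2 value of 6 gene lists per array (vertical axis) by day in WT (blue) and KO (orange), with each point 1 array and black bars the mean ± SD of 3 arrays. The SRF cytoskeletal target means of KO arrays lie under those of WT arrays on every day, while sarcomere genes rise and cell cycle genes fall over time in both.

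Differentiation changed many genes in WT cells. At day 1, 2963 genes were higher and 3397 lower than at day 0, and at day 3, 3988 and 3850. The fast myosin heavy chain gene Myh4 rose from 5.04 ± 0.22 at day 0 to 10.57 ± 0.50 at day 3 (log2 change 5.53, adjusted p = 3.79e-11). Myoz1 (4.78), Mlip (4.74), Mybpc2 (4.68) and the sodium pump subunit gene Atp1b2 (4.51) followed. At day 1 the largest rises were those of the muscle protease gene Capn3 (4.03), Atp1b2 (3.83), Ablim3 (3.72), Myh4 (3.51) and Gal3st2b (3.49). Selp, which encodes P-selectin, fell from 9.88 ± 0.22 to 4.64 ± 0.14 at day 1 and 3.91 ± 0.56 at day 3. Prl2c3 changed by -5.26, the adhesion receptor gene Adgrg3 by -4.99, Dynap by -4.82 and the scaffold gene Akap12 by -4.53 at day 3, and Fosl1 changed by -4.00 at day 1. The day 0 means of Myoz1, Mybpc2, Capn3 and Egr2 and the day 3 means of Selp, Prl2c3, Adgrg3 and Akap12 lay below the array medians. So did the day 1 means of Selp, Prl2c3 and Adgrg3.

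In WT cells 52 of 53 sarcomere genes rose on both days, with medians of 1.90 at day 1 and 2.23 at day 3 (camera adjusted p = 1.25e-32 and 9.98e-30, and adjusted p = 0.0505 and 0.0643 with an estimated correlation). All 38 cell cycle genes fell, with medians of -2.52 and -3.33 (adjusted p = 4.19e-35 and 5.73e-37, and 0.0301 and 0.0238 with an estimated correlation). Top2a, the topoisomerase of dividing cells, went from 9.80 ± 0.16 to 5.76 ± 0.80 at day 3. Cholesterol synthesis genes rose in 20 of 20 cases at day 1 and 17 of 20 at day 3, with Insig1 (2.23) and Dhcr7 (2.12) leading at day 3, and medians of 1.82 and 1.28 (adjusted p = 0.0013 and 0.0123 with an estimated correlation). Of the 38 matrix genes 18 fell at day 1 and 22 at day 3, among them Thbs1 (-3.88), Col3a1 (-3.28) and Fn1 (-3.23). Of the 39 SRF cytoskeletal targets 22 fell and 6 rose by day 3, with falls in Flna (-3.99), Tagln2 (-3.43), Tes (-3.19) and Tpm4 (-3.09), and a median of -0.62 (adjusted p = 1.76e-05, and 0.0238 with an estimated correlation). The immediate early list rose in 12 of 17 members by day 3, among them Egr3 (2.22), Egr2 (1.70), Egr1 (1.58) and Fos (1.55), with a call that was lost with an estimated correlation (adjusted p = 0.00105 and adjusted p = 0.122). Of 31 actin nucleation genes 17 fell by day 3 (median -0.36, adjusted p = 1.76e-05, and 0.0123 with an estimated correlation), and of 21 satellite cell genes 12 fell and 2 rose (median -0.86, adjusted p = 0.000445, and 0.0311 with an estimated correlation). The fusion list went both ways, with 10 genes higher, such as Cav3 (3.36), Dysf (2.41) and Mymx (1.82), and 10 lower, such as Kirrel (-2.83).

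In KO cells, 2983 genes were higher and 3373 lower at day 1 than at day 0, and 4233 and 4074 at day 3. Sarcomere genes rose in 51 of 53 cases at day 1 and 52 at day 3, with medians of 2.29 and 2.68 (adjusted p = 0.0368 and 0.0496 with an estimated correlation), and all 38 cell cycle genes fell on both days. Of the 17 immediate early targets 5 rose and 1 fell by day 3, with a median of 0.31, and the list was not called (adjusted p = 0.0932). Myh4 rose by 5.90 by day 3, the sarcolipin gene Sln by 5.96, Ckm by 5.10, Mlip by 5.04 and Ppp1r27 by 4.91. Selp changed by -5.62, the mitotic kinesin gene Kif23 by -5.47, Anln by -5.31, Vcan, which encodes the matrix proteoglycan versican, by -5.26 and Adgrg3 by -5.19. The day 0 mean of Mlip and the day 3 means of Selp, Kif23, Anln and Adgrg3 lay below the array medians. Of the genes higher in WT at day 3, 3042 were also higher in KO, or 76.3% (728 for independent lists), and of those lower 3312, or 86% (677 for independent lists). Here too the calls share 1 estimate of the spread per gene. There were 9 genes called in opposite directions. Across genes the day 3 responses of WT and KO, from separate arrays, correlated at r = 0.934, and those of day 1 at 0.923.

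The difference of the KO effect between days was tested directly. Between day 1 and day 0 it was called for 2 genes, Acta2, whose KO effect was 1.68 higher at day 1 (SE 0.22, adjusted p = 0.014), and Traf3ip3 (0.95, adjusted p = 0.0396). The Acta2 mean of day 1 WT arrays, 12.12 ± 0.12, lay 0.54 under the highest named genes of those arrays. Between day 3 and day 0 it was called for 27 genes, 9 higher and 18 lower. The KO effect on Acta2 went from -2.24 at day 0 to -0.67 at day 3 (difference 1.58, adjusted p = 0.00944) and that on Cnn2 from -2.30 to -0.91 (difference 1.39, adjusted p = 0.0269). The effect on Actb went the other way, from -0.32 to -1.18 (difference -0.86, adjusted p = 0.0215), and that on Egr3 from 0.42 to -1.98 (difference -2.40, adjusted p = 0.0132). Timp1 (-1.45), Plk4, a kinase of centriole duplication (-1.51), Ly6d (-1.73) and Aqp3 (-1.58) also had lower KO effects at day 3, and Ppp1r27 (2.12), Fibin (1.56) and Slc25a10 (1.21) higher ones. Traf3ip3 in KO and Ly6d and Aqp3 in WT at day 0, Plk4 in KO at day 3 and Aqp3 in both at day 3 had means below the array medians. The Egr3 values of day 0 lay little above those medians, from 4.73 to 4.96 in WT and from 4.96 to 5.46 in KO. A fall of Egr3 in KO may therefore not be visible at day 0. The Actb mean of day 0 WT arrays, 12.94 ± 0.05, lay among the highest values of those arrays. The day 3 count fell from 27 to 10, 16 or 12 without day 0 WT replicates 1, 2 or 3, to 12 without day 0 KO replicate 1 or 3, to 16 without day 3 WT replicate 2 and to 15 without day 3 KO replicate 3. With the replicate block within each day it was 47, 23 higher and 24 lower. For the 2 genes of day 1 it was 0, and their call was lost in 6 (Acta2) and 17 (Traf3ip3) of the 18 fits that left out 1 array.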

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

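All splits of the arrays and all tests of explanations given in this part were chosen after the results were seen, while the tests of the differences themselves were planned. The difference of the KO effect between days passed its test for 2 genes between days 1 and 0 and for 27 genes between days 3 and 0. When the KO and WT labels were redrawn within each day, 9 of 100 draws, the real one included, gave at least 2 genes for days 1 and 0, so chance is not excluded there, and the highest other draw gave 137. For days 3 and 0, 4 of 100 draws gave at least 27 genes, and the highest other draw gave 159. With day 3 labels exchanged only within same-numbered pairs, 2 of all 80 distinct relabellings gave at least 27 genes, again with 159 as the highest other. These highest draws exchange all labels of 1 day, which adds the effects of both days instead of subtracting them, and they stay in the counts. Redrawn labels stand for no KO effect on either day, and not for an equal effect on both. The shares for days 3 and 0, though under 0.05, therefore cannot exclude chance for a difference between days.

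Between days 1 and 0 the KO effect differed by 1.68 for Acta2 and 0.95 for Traf3ip3. Between days 3 and 0 it differed by 2.12 for Ppp1r27, 1.58 for Acta2, 1.56 for Fibin, 1.39 for Cnn2 and 1.21 for Slc25a10. In the other direction it differed by -2.40 for Egr3, -1.73 for Ly6d, -1.58 for Aqp3, -1.51 for Plk4, -1.45 for Timp1 and -0.86 for Actb. The WT mean of Actb at day 0 lies 0.01 under the highest values of those arrays. Actb itself is the highest or nearly the highest gene there, so this distance is near 0 in any case and does not show saturation. Whether signal close to the top of the scale compressed the day 0 effect of Actb stays open. Of the other 26 genes that differed between days 3 and 0, 0 had a group mean at day 0 or 3 within 1 of the top. The highest mean was 11.3, that of Acta2 in WT at day 3. At this limit the means argue against signal close to the top of the scale for the genes other than Acta2. The limit is looser than the distance asked of Actb and of Acta2 at day 1. Acta2 would not reach that distance at day 3, so compression stays open for it there. It stays open too for the Acta2 difference between days 1 and 0, since the day 1 WT mean lies 0.54 under the highest named genes of those arrays. A different use of SRF before and during differentiation stays open as a biological explanation and was not tested.

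Among gene lists, the median KO effect differed between days 1 and 0 by 0.24 for myogenic transcription factors and -0.16 for interferon response genes, both also with an estimated correlation (adjusted p = 0.00643 and 0.0464). The interferon call was lost with the preset correlation without day 0 WT replicate 3 (adjusted p = 0.0522) or day 0 KO replicate 3 (adjusted p = 0.0527). With the preset correlation alone it differed by 0.09 for SRF cytoskeletal targets, 0.29 for sarcomere genes and -0.17 for cholesterol synthesis (adjusted p = 0.405, 0.532 and 0.532 with an estimated correlation). Between days 3 and 0 it differed by 0.45 for cholesterol synthesis, also with an estimated correlation (adjusted p = 0.0268). With the preset correlation alone it differed by 0.12 for SRF cytoskeletal targets, -0.26 for immediate early targets, 0.36 for sarcomere genes, -0.47 for cell cycle genes, -0.14 for p53 targets and -0.17 for extracellular matrix genes (adjusted p from 0.278 to 0.623 with an estimated correlation). Several of these preset calls were also lost without 1 array. For SRF cytoskeletal targets the highest adjusted p was 0.301, without day 1 WT replicate 1, between days 1 and 0, and 0.349, without day 3 KO replicate 1, between days 3 and 0. For cholesterol synthesis between days 1 and 0 it was 0.269 without day 1 WT replicate 3. Between days 3 and 0 it was 0.146 for p53 targets without day 3 WT replicate 3 and 0.0677 for extracellular matrix without day 3 WT replicate 2. Medians between days 3 and 0 also moved with single arrays. That of cell cycle genes was -0.21 without day 3 WT replicate 1, and that of p53 targets -0.22 without it. That of immediate early targets was -0.11 without day 0 KO replicate 1 and -0.15 without day 0 WT replicate 3. That of matrix genes was -0.11 and -0.07 without the same arrays. For SRF cytoskeletal targets the medians were 0.21, and 0.15 between days 1 and 0, without day 0 KO replicate 1. For cholesterol synthesis between days 1 and 0 it was -0.10 without day 0 KO replicate 2.

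The sarcomere differences start from the lower list in KO at day 0, where the median was -0.42. Without day 0 KO replicate 1 that median was -0.13, still called with the preset correlation (adjusted p = 9.7e-06), and the differences were 0.05 between days 1 and 0 (preset adjusted p = 0.397) and 0.09 between days 3 and 0 (preset adjusted p = 0.0528). Without day 0 WT replicate 3 they were 0.18 and 0.23, and the difference between days 1 and 0 was 0.45, 0.48 and 0.47 without day 0 WT replicate 1, KO replicate 2 and KO replicate 3. Day 0 KO replicate 1 alone may therefore account for much of the size of the pattern, and not for the call that remains. The list mean of replicate 1 was the lowest in WT too, at 8.09 against 8.47 and 8.61, as was 7.39 against 8.24 and 8.20 in KO. Leaving out KO replicate 1 alone keeps the low WT array, so a shift shared by both arrays cannot be told apart from one of the KO array. Under quantile, median and cyclic loess scaling the median nearest to 0 was -0.42, but these scalings move the values too little to decide about the scaling of the arrays, which stays open. Whether the culture of day 0 KO replicate 1 differentiated later than the others, or its RNA differed, was not tested.

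Of the 2021 probe sets without a gene name, which the comparisons do not use, 7 passed the threshold for KO against WT at day 0, 3 at day 1 and 10 at day 3. Groups of 3 arrays are too small for a test of single far values.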

How the results depend on the processing

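The replicate block within each day and the removal of the 3 arrays farthest from their groups were chosen after seeing the data, and the other alternatives before. No named gene, called list or Srf difference reversed under any alternative. For KO against WT, every called gene and Srf had the 3 arrays of one group all above those of the other. Of the alternatives, only the scalings could have reversed these, so their unchanged direction elsewhere was fixed in advance. Whether higher or lower calls were more numerous over time at day 3 did turn, for example to 3704 higher and 4037 lower in WT and 3891 and 4255 in KO with cyclic loess. With only the arrays of the groups compared, the counts for KO against WT were 48, 9 and 20 at days 0, 1 and 3, and those for the differences 0 (days 1 and 0) and 15 (days 3 and 0), with fewer arrays behind each variance. With a log2 change of at least 1 they were 40, 13 and 44 for KO against WT, 2005 and 2682 over time in WT, 2044 and 2858 in KO, 1 for the difference of days 1 and 0, and 3 genes on all 3 days. At an adjusted p under 0.01 they were 45, 11 and 37, with 0 and 5 for the differences. Among genes above the median by mean level, where fewer genes are tested, 37 were called at day 1, 158 at day 3 and 11 on all 3 days. Trend and robust settings gave 38 at day 1 and 10 on all 3 days, and array weights 59 and 9, and the cause was not tested. The replicate block gave 1 gene for the difference of days 1 and 0. The replicate block within each day gave 40 genes at day 1, 188 at day 3, and 0 and 47 for the differences, and it moved no other count by over 1.5 times. It added 2 list calls, myoblast fusion at day 0 (adjusted p = 0.00964) and the difference of days 3 and 0 for myogenic transcription factors (adjusted p = 0.0258), both with the preset correlation, and ended none. Without a block neither was called with the preset correlation, and with an estimated one these 2 lists had adjusted p = 0.121 and 0.278. The last 2 values differ from those of the block in the correlation too, so they do not show the effect of the block alone. Without the 3 farthest arrays there were 10 at day 1, 57 at day 3, and 1 for the difference of days 1 and 0. Of the 66 list tests of KO against WT, 20 were called with the preset correlation, 11 with an estimated one and 14 with fry.

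Leaving out each array in turn gave 56 to 123 genes at day 0, 8 to 32 at day 1, 50 to 217 at day 3, 0 to 3 for the difference of days 1 and 0, and 10 to 36 for that of days 3 and 0. The highest counts at day 0 and for both differences came without day 0 KO replicate 2. The difference of days 1 and 0 had 0 genes without day 0 WT replicate 3 or KO replicate 3, or without day 1 WT replicates 1 or 2 or KO replicates 2 or 3. Over time the counts stayed between 5538 and 6596 (WT, day 1), 6951 and 8007 (WT, day 3), 5424 and 6560 (KO, day 1), and 7272 and 8519 (KO, day 3). From 4 to 7 genes were lower or higher on all 3 days, and 17 to 22 list tests were called. The Srf difference lay between -0.50 and -0.30 at day 0, -0.46 and -0.35 at day 1, and -0.59 and -0.38 at day 3. For named genes in KO against WT and the differences, 83 results took 2650 values under the alternatives. Of these, 2190 kept their direction and side of the threshold and 460 kept the direction and lost the call. Many of the settings leave out an array of a day that a result does not use, which alters its p-value and not its change. The share kept is therefore a weak measure of stability. Of the 83 results, 28 never lost the call. Of 832 values of called lists, 77 lost the call. Under the scalings camera was not run again and only the sign of the list median was compared. Those values, which are among the 832, therefore do not show whether a call held under another scaling. For KO against WT, the median change of all genes lay between -0.02 and 0.006 under the other scalings. The average over several probe sets of a gene was not run, since no gene has several.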

Other observations

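The gene families, the splits of the arrays and the tests of explanations in this part were chosen after the results were seen, while the counts and gene calls they concern come from the planned comparisons. Gene families were put together by symbol, 15 of them, and compared over time. Of 34 subunits of respiratory complex I, the entry point of the mitochondrial electron transport chain, 17 were higher at day 1 and 30 at day 3 in WT, with medians of 0.34 and 0.57. In KO, 23 and 32 were higher, with medians of 0.42 and 0.73. Of 76 mitochondrial ribosomal proteins, 27 were higher and 3 lower at day 3 in WT, and 52 and 1 in KO. Of 32 replication-dependent histones, which are made during DNA replication, 17 were lower and 5 higher at day 3 in WT, and 20 and 7 in KO. For complex I at day 3 the camera adjusted p was 2.57e-10 in WT and 3.11e-13 in KO with the preset correlation, and with an estimated correlation the calls were lost (adjusted p = 0.365 and 0.294). Between KO and WT, 0 genes of these 3 families were called on any day. As sets, 13 of 75 tests of the 15 families between KO and WT and of differences between days were called with the preset correlation, all 13 higher, and 0 with an estimated one (adjusted p of the 13 from 0.157 to 0.688). At day 3 these were mitochondrial ribosomal proteins (median 0.15, adjusted p = 1.31e-08), complex I (0.11, 0.000206), cytochrome c oxidase (0.21, 0.00198) and solute carriers of family 25 (0.07, 0.0338). At day 1 they were glutathione transferases (0.14, 0.000451), proteasome subunits (0.09, 0.000451), mitochondrial ribosomal proteins (0.06, 0.00195) and ribosomal proteins (0.08, 0.00655). Between days 3 and 0 the KO effect differed for mitochondrial ribosomal proteins (0.20, 4.81e-10), complex I (0.16, 0.00012) and cytochrome c oxidase (0.22, 0.0028), and between days 1 and 0 for the first 2 of these (0.12, 2.22e-05, and 0.09, 0.0311).

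For KO against WT the arrays of a day allow 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes on each day. The real counts were 114, 21 and 103 at days 0, 1 and 3, and the highest other splits gave 0, 0 and 67. The split with 67 genes set WT replicates 1 and 2 and KO replicate 1 against the rest. It keeps the same-numbered pairs 1 and 3 together, and among day 3 splits that part every pair the highest other gave 0. Over time the real counts were 6360 and 7838 in WT and 6356 and 8307 in KO, and the highest other splits gave 0, 1, 0 and 0. Each other split over time mixes the days on both sides, which puts the large day effect into the spread. Counts near 0 were therefore all but fixed there and decide nothing about chance. For genes in the same direction on all 3 days, 1 of 100 draws, the real one, gave 5 genes, and the highest other gave 0. With day 3 labels exchanged only within pairs it was again 1 of 100, with 0 as the highest other. Every other split of day 0 or day 1 alone had given 0 genes, so both results were all but fixed and decide nothing about chance.

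Several of the genes higher in KO at day 0 are best known from epithelia. They were Ly6d, Krt18, Lcn2, Aqp3, Wfdc2 (1.29), Dsp (1.26), Calm4 (1.26) and Slpi (1.19), a group chosen after its values were seen. The WT means of Ly6d, Lcn2, Aqp3, Wfdc2, Dsp and Slpi lay below the array medians, so these changes are lower bounds at most. Leaving out any 1 array of day 0 left each of these genes with a change of at least 1.06, but genes chosen for large changes decide nothing about the part of single arrays, which stays open. Epithelial cells among the KO cells could bring such transcripts, and sorting for GFP does not select a cell type. Of 30 epithelial markers 2 were called, Krt18 and Dsp, and the list had a median of 0.07 and an upper quartile of 0.22, far under the changes of those genes. Krt8, the usual partner of Krt18, differed by -0.10 (5.13 in WT and 5.03 in KO), Epcam by 0.03 and Cdh1 by 0.22. Perp (0.93), Krt19 (0.90), Spint1 (0.64) and Krt7 (0.63) had higher values that missed the threshold. Only 12 of the 30 markers lie above the median level of all genes in WT, so the list argues against a large share of such cells and a small one stays open. An effect of Srf loss or of Cre within the muscle cells stays open too and was not tested.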
